A study of Arabidopsis thaliana with 8 samples.

How the data were processed

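RNA was measured by sequencing in shoot apices of Arabidopsis thaliana, in wild type and in a line that expresses an artificial microRNA against PECT1 from the FD promoter, called the knockdown line here. Samples were taken at 10 and 16 days of age, at ZT 8 (8 hours after lights on), from plants kept in short days at 23 °C. Per the labels' protocols, total RNA was isolated with trizol and made into strand-specific mRNA libraries. The design has 4 groups with 2 libraries each, 8 in all, and groups and replicate numbers were taken from the sample titles. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, part of which may be technical.

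The authors deposited a table of RPKM values (reads per kilobase of transcript and per M of reads), as the file headers call them, for 27655 loci in the 8 libraries. The name of the file says RPM, and the analysis plan had assumed RPM, but the low values are steps of 1 read divided by the exon length of the gene, so the values were used as RPKM and limits planned in RPM were applied to RPKM. The genome build was TAIR10, per the submitters' processing notes; the aligner, the counting tool and its treatment of strand and shared reads are not given in the sources used here. The authors also deposited 4 tables of changed genes (higher and lower at each age), each with a linear fold and a p-value per locus, per the file headers. In the tables of lower genes the authors' fold is written with a minus sign, which makes it a signed score, not a ratio. The test behind the authors' p-values is not given in the sources used here. The log2 column of these tables was not used, as the fold was taken. Locus names that stand without any other value in 3 of these tables (3, 5 and 6 cells) were left out.

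Gene symbols, positions and exon lengths came from a RefSeq annotation of the TAIR10.1 assembly, which matched 27445 of the 27655 loci; the other 210 are organelle loci. From the steps in the low values, the depth was estimated at 15.46 to 18.17 M reads per library. With these depths and the exon lengths, 81.0% to 85.9% of the low values lay within 0.1 of a whole read, so reads were estimated, not recovered, and no test for read counts was run as the leading test.

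The leading test was limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(RPKM + 1). Genes with at least 1 RPKM in at least 2 of the 8 libraries were tested, 17467 in all. The model had a coefficient per group, and the 4 groups shared 1 estimate of the spread, with 4 residual and 5.8 prior degrees of freedom. Contrasts were the knockdown line against wild type at day 10, at day 16 and as the mean of both ages, the difference of that effect between the ages (interaction), and day 16 against day 10 within each genotype. The limma tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 with no limit on fold. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. "Rose" and "fell" are used only of genes that passed.

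Each gene list was fixed before the data were examined, and so were the tests, the named-gene rule and the alternatives unless stated otherwise. The 23 lists cover phospholipid synthesis, flowering promoters, floral repressors, SPL factors, floral organ identity, shoot meristem and organ boundary, circadian clock, cell division, endoplasmic reticulum stress, autophagy, heat shock, salicylic acid defence, jasmonate and wounding, touch and rapid stress response, abscisic acid with cold and drought, phosphate starvation, gibberellin, auxin, glucosinolates, flavonoids, and markers of leaf mesophyll, vasculature and root. Of 408 loci written, 11 were dropped because the annotation pairs the locus with another symbol. Among them were CEK1, CEK4, SDC, PMT1 and PMT2 of the phospholipid list, so the results of that list do not cover these genes. Lists were tested with camera (limma) at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast. Camera with a correlation estimated from the data and fry (limma) were run as alternatives. Members were also tested with the adjustment over the list alone.

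The named genes were PECT1 and FD, then at each age the 8 genes with the largest rise and the 8 with the largest fall among those that passed, had a mean of at least 5 RPKM in the higher group, and had both knockdown libraries on the same side of both wild-type libraries. Empty places were filled by the genes with the smallest p, and the text says that these did not pass. Up to 4 members per list that passed adjusted over the list alone were added, and FT, SOC1, FUL, AP1, LFY, SPL3, SPL4, SPL5, SVP and FLC whatever their p. For the interaction and for age the rule took 4 per direction and passing members of the flowering lists, and from each of the authors' tables the 3 largest folds with a mean of at least 5 RPKM in the higher group. Any other gene the text names was chosen after its values were seen, among members of the lists or as stated.

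Alternatives were a pseudocount of 0.25 or 4, no filter or a filter at 5 RPKM, 3 other scalings between libraries (median-of-ratios, quantile, and RPKM without organelle loci and the 20 most abundant genes), limma without trend or with robust moderation, the replicate number as a block, fits on only the groups compared, a minimum log2 fold change of 1, and each library left out in turn. A limma voom fit on reads estimated from RPKM, exon length and depth was added after the data had been seen.

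The fitting code was tested on simulated data for the comparison at day 10 with 16750 genes, 2 libraries per group and 50 changed genes per fold. It called 14% of genes changed 1.5-fold, 70% of genes changed 2-fold, 96% of genes changed 4-fold and 100% of genes changed 8-fold, with 9 false calls. The changed genes were drawn only from genes above a minimum of reads. Their spread was set around the median dispersion between replicates of the real data (0.0161). A median over estimates from 2 libraries each tends to lie below the true spread, so these rates may be too high for typical genes too. They do not hold for genes with few reads or a wider spread. Among 100 random lists of unchanged genes, camera gave 4 an unadjusted p under 0.05. Summaries, exact tests and plots used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

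Values of genes taken to have near-identical copies (SPL13A and SPL13B, PCC1 and AT3G22235, AT1G67860 and AT1G67865, and the RBCS genes) are uncertain, because reads may have been split between the copies. Their sequences were not compared here. The same holds for named genes that overlap another locus in the annotation, which are AT1G25180, AT1G73650, BCAT4, IMD1, CHS, AT5G25570, SPL9, AHP4, CDEF1, AT5G55450, AT5G51190, SPL3, AT1G48750, FLC, SPL13A, SPL4, SPL5, AT1G32630 and AT4G02725. A value of 0 can be a failed assignment in this table, since some genes stand at 0 in 1 library and at 5 RPKM or more in the other library of the same group (3, 1, 17 and 9 genes in wild type at day 10, wild type at day 16, knockdown at day 10 and knockdown at day 16). Genes with values of 0 are therefore given library by library, as listed at 0.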

Results

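The 8 RNA-seq libraries came from shoot apices of Arabidopsis thaliana, 2 each of wild type and of the knockdown line at day 10 and at day 16. PECT1 encodes the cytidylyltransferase of the phosphatidylethanolamine pathway, and FD, whose promoter drives the artificial microRNA, encodes a bZIP factor of the shoot apex that partners with the florigen FT. This species flowers later in short days than in long days. The comparisons ask which transcripts of the apex differ between the genotypes under these conditions, and whether this depends on age. Estimated depth was 15.46 to 18.17 M reads, and 16180 to 16883 loci per library had at least 1 RPKM. The 2 libraries of a group correlated across genes at a Pearson r of 0.968 to 0.978 on log2(RPKM + 1). They differed by more than sampling noise, with a chi-square per degree of freedom of 20.3 to 33.0 on estimated reads.

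Summed RPKM of leaf mesophyll markers ranged from 44319 to 59183 between libraries, that of vascular markers from 137 to 205, and that of root markers from 0.1 to 0.5. Replicate 1 of the knockdown at day 16 stood apart in its organelle transcripts and in its share of nuclear reads. Its mitochondrial sum was 264 RPKM against 106 to 159 in the other libraries, and its chloroplast sum was 1817 RPKM against 1071 to 1581. An estimated 85.4% of its reads came from nuclear genes, against 93.1% to 95.7%. Organelle sums of this size, per kilobase and per M of reads, are too small to account for that gap. The source of the gap was not tested.

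PECT1 (AT2G38670, chromosome 2, 16168712 to 16171918 in TAIR10.1) was at 40.7 and 39.2 RPKM in wild type and 35.3 and 37.1 RPKM in the knockdown line at day 10. At day 16 it was at 40.4 and 41.3 RPKM in wild type and 34.4 and 37.0 RPKM in the knockdown line. The log2 fold change was -0.14 ± 0.145 (SE) at day 10 and -0.19 ± 0.145 at day 16, and neither passed limma (Benjamini-Hochberg adjusted p = 0.860 and 0.842). All 4 knockdown values lay below all 4 wild-type values, but this order did not hold after median-of-ratios scaling, where replicate 1 of the knockdown at day 16 was at 38.9 RPKM and wild type ranged from 37.6 to 42.1 RPKM. FD (AT4G35900), a marker of the cells in which the microRNA is made, had 1.98 ± 0.354 RPKM in wild type and 1.14 ± 0.127 in the knockdown line at day 10 (SD, n = 2), and 2.06 ± 0.453 and 2.53 ± 0.0566 at day 16. Its differences did not pass limma either (adjusted p = 0.753 and 0.888). The FD promoter was expected to drive the microRNA in only part of the cells of an apex. Values of whole apices therefore cannot tell whether PECT1 fell in those cells.

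**Figure D1:**
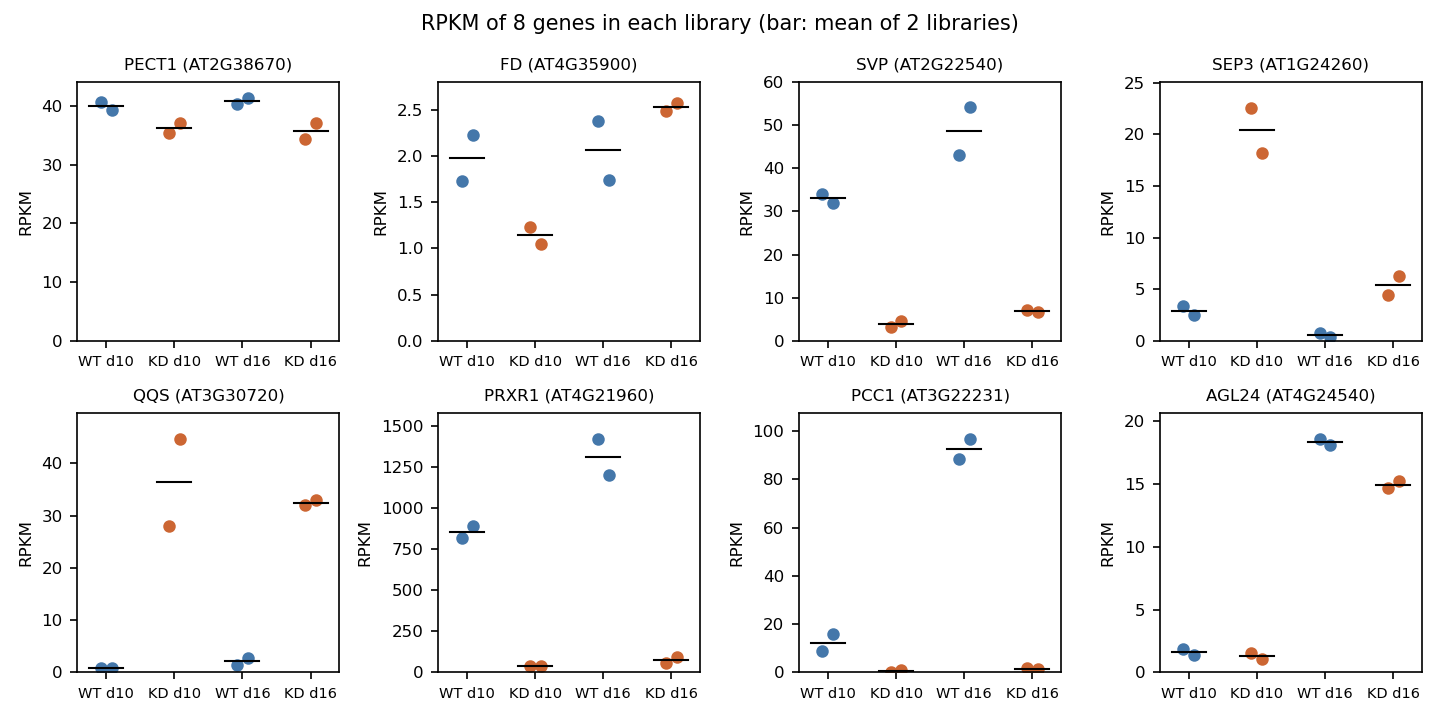
RPKM (vertical axis, from 0) of 8 genes in wild type (WT) and the knockdown line (KD) at day 10 (d10) and day 16 (d16), with a point per library and a bar at the group mean. PECT1 differs little between genotypes, SVP and PRXR1 are low and SEP3 and QQS high in the knockdown line at both ages, and AGL24 differs by age.

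At day 10, SVP, a MADS-box repressor of flowering (AT2G22540, chromosome 2, 9579647 to 9583901 in TAIR10.1), fell from 33.0 ± 1.46 RPKM in wild type to 3.85 ± 0.990 RPKM in the knockdown line (SD, n = 2). SEP3, a MADS-box factor of floral organ identity (AT1G24260, chromosome 1, 8593536 to 8596123), rose from 2.93 ± 0.629 to 20.4 ± 3.11 RPKM. QQS, an orphan gene that affects starch content (AT3G30720, chromosome 3, 12349047 to 12349933), rose from 0.83 ± 0.0141 to 36.4 ± 11.7 RPKM. The peroxidase gene PRXR1 (AT4G21960, chromosome 4, 11646109 to 11648644) fell from 854 ± 53.3 to 40.6 ± 0.269 RPKM, and PIN1AT, a parvulin-type prolyl isomerase gene (AT2G18040, chromosome 2, 7841940 to 7843942), fell from 86.1 ± 2.43 to 6.33 ± 2.21 RPKM.

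In limma with Benjamini-Hochberg adjustment, 13 of 17467 genes passed at day 10, 4 higher and 9 lower in the knockdown line. At an unadjusted p under 0.05 there were 1163 genes, where chance alone gives 873. The log2 fold change was -2.83 ± 0.205 (SE) for SVP (adjusted p = 0.000340), 2.45 ± 0.258 for SEP3 (0.00552), 4.32 ± 0.273 for QQS (0.000116), -4.36 ± 0.193 for PRXR1 (7.9e-06) and -3.60 ± 0.218 for PIN1AT (0.000102). AT2G13547 also rose, listed at 0 in both wild-type libraries and at 9.59 and 8.64 RPKM in the knockdown line (adjusted p = 0.000880). So did AT1G25180, at 0.540 and 0.990 against 10.5 and 10.3 RPKM (0.00278). AT3G01345 fell from 91.6 ± 9.89 to 0.665 ± 0.474 RPKM (adjusted p = 7.9e-06). PCC1, a gene named for its control by pathogens and the circadian clock, was at 8.90 and 15.9 RPKM in wild type, listed at 0 and at 0.820 RPKM in the knockdown line, and passed (0.00443). AT3G51000 (5.96 to 0.745 RPKM), AT1G73650 (14.7 to 2.97 RPKM), AT3G16660 (30.4 to 6.93 RPKM) and AT2G31440 (26.1 to 10.4 RPKM) completed the genes that fell. AT1G67860, AT5G35525, AT1G77940 and AT1G16850 filled the empty places of the naming rule and did not pass, with positive log2 fold changes of 0.67 to 1.76 (adjusted p = 0.0807 to 0.275).

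Among the fixed lists, the floral repressors were lower as a group at day 10 (camera adjusted p = 0.00467; adjusted p = 0.426 with an estimated correlation). Of 14 measured members, 1 fell, 0 rose and 10 had a negative fold change. Adjusted over the list alone, 2 were lower, SVP and TEM2, a repressor of FT, at 27.8 ± 3.44 and 13.6 ± 7.26 RPKM (limma adjusted p = 0.0497). Floral organ identity genes were higher (adjusted p = 0.00752; adjusted p = 0.426 with an estimated correlation), which rested on 4 measured members, with SEP3 the only member that passed. Flavonoid and anthocyanin genes were lower (8.6e-06; adjusted p = 0.426 with an estimated correlation). None of their 10 members passed over all genes, and 5 were lower adjusted over the list alone, among them CHS, the entry enzyme of the pathway (39.8 ± 14.1 and 16.5 ± 1.93 RPKM), DFR (2.42 ± 0.297 and 0.310 ± 0.113 RPKM), LDOX and FLS1.

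Glucosinolate genes were lower as well (camera adjusted p = 0.0140; adjusted p = 0.632 with an estimated correlation), with 7 of 15 members positive and 8 negative. Adjusted over the list alone, 4 members of the methionine-derived branch were lower, namely BCAT4 (61.1 ± 6.49 and 15.8 ± 2.39 RPKM), MAM1, IMD1 and CYP83A1. Cell division genes had 19 of 21 members negative and a median log2 fold change of -0.17 (adjusted p = 0.0327; adjusted p = 0.632 with an estimated correlation), with no member passing. Markers of leaf mesophyll were lower (0.00467; adjusted p = 0.632 with an estimated correlation) and those of vasculature higher (0.0249; adjusted p = 0.632 with an estimated correlation), so these tissue markers moved alongside the groups above. The mesophyll call changed sign without replicate 2 of the knockdown at day 10 (adjusted p = 0.688). With each library left out in turn, the vascular call held in 6 of 8 fits, cell division in 5 (adjusted p up to 0.311) and glucosinolate genes in 4 (up to 0.784).

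The other 15 lists measured at day 10 were not called (camera adjusted p = 0.0594 to 0.820), and root markers had 0 tested members. Among the flowering genes named in advance, SOC1 had 4.45 ± 0.644 RPKM in wild type and 6.84 ± 1.00 in the knockdown line, SPL3 5.50 ± 0.106 and 7.59 ± 1.82, SPL4 1.65 ± 0.297 and 0.975 ± 0.714, FLC 6.67 ± 2.28 and 4.72 ± 0.304, and LFY 0.580 ± 0.127 and 0.975 ± 0.248. None of them passed in limma (adjusted p = 0.752 to 0.849). FT was listed at 0 in all 4 wild-type libraries of both ages. In the knockdown line it was at 0 and 0.180 RPKM at day 10 and at 0.0700 and 0.280 RPKM at day 16. AP1 was listed at 0 in all libraries but 1 of the knockdown line at day 16 with 0.0900 RPKM. FT, AP1, FUL and SPL5 were too low to be tested. The number of genes passing at day 10 was 7 without replicate 2 of wild type at day 10, 26 without replicate 2 of the knockdown at day 10, and 7 with voom on estimated reads. SVP, PRXR1 and PIN1AT passed under all 20 alternatives of this comparison. QQS, AT2G13547 and AT1G25180 did not pass with voom (adjusted p = 0.0936, 0.391 and 0.0840), and SEP3 did not pass without replicate 2 of wild type (0.0959), without replicate 1 of the knockdown (0.0616) or with no filter (0.0535). AT3G51000 passed under 12 of the 20, PCC1 and AT3G16660 under 17 each and AT1G73650 under 18, with PCC1 at an adjusted p of 0.670 with voom.

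At day 16, SVP again fell, from 48.6 ± 7.79 to 6.88 ± 0.290 RPKM, and SEP3 rose from 0.560 ± 0.269 to 5.38 ± 1.27 RPKM (SD, n = 2). QQS rose from 2.14 ± 0.926 to 32.5 ± 0.672 RPKM, PRXR1 fell from 1312 ± 153 to 76.5 ± 23.8 RPKM, and PIN1AT fell from 79.2 ± 4.88 to 3.3 ± 0.453 RPKM. PCC1 fell from 92.5 ± 5.80 to 1.52 ± 0.339 RPKM and its neighbour AT3G22235 from 83.6 ± 3.87 to 1.32 ± 1.19 RPKM. GA20OX2, an enzyme of gibberellin synthesis, had 2.82 ± 0.658 RPKM in wild type and 10.7 ± 3.99 in the knockdown line, a difference that passed adjusted over the list alone (limma adjusted p = 0.00242) but not over all genes (adjusted p = 0.121).

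In limma, 20 genes passed at day 16, 4 higher and 16 lower, against 1112 (246 higher and 866 lower) at an unadjusted p under 0.05. The median log2 fold change of all genes at this age was -0.11 and became 0.008 with median-of-ratios scaling. It was 0.01 without replicate 1 and -0.242 without replicate 2 of the knockdown at day 16, so the shift to lower values followed replicate 1. The log2 fold change was -2.65 ± 0.205 (SE) for SVP (adjusted p = 0.000446), 2.03 ± 0.258 for SEP3 (0.0190), 3.45 ± 0.273 for QQS (0.000474), -4.11 ± 0.193 for PRXR1 (1.4e-05), -5.22 ± 0.329 for PCC1 (0.000114), -5.29 ± 0.374 for AT3G22235 (0.000266) and -4.22 ± 0.218 for PIN1AT (2.2e-05). AT2G13547 also rose, listed at 0 and 0.210 RPKM in wild type and at 10.3 and 16.8 RPKM in the knockdown line (adjusted p = 0.000348). So did AT1G25180, listed at 0.370 and 0 against 7.19 and 7.11 RPKM (0.00140). AT3G01345 was at 53.1 and 58.1 RPKM in wild type and listed at 0 and 0.240 in the knockdown line (1.1e-05). AT2G25510 (log2 fold change -2.54 ± 0.221, adjusted p = 0.000989) and AT5G25570 (-2.23 ± 0.298, 0.0256) completed the largest falls. EBP, GA20OX2, AT3G53980 and AT2G19970 filled the empty places among higher genes without passing, with log2 fold changes of 0.97 to 1.59 (adjusted p = 0.109 to 0.276).

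Floral organ identity genes were higher at day 16 (camera adjusted p = 0.000826; adjusted p = 0.569 with an estimated correlation), again with SEP3 as the only one of 4 members that passed. Flowering promoters were called higher (0.0482; adjusted p = 0.569 with an estimated correlation), with 5 of 7 members positive and 0 passing. SOC1 had 9.24 ± 0.446 and 15.6 ± 5.25 RPKM. Salicylic acid defence genes were lower, with 10 of 11 members negative (0.0393; adjusted p = 0.569 with an estimated correlation). Auxin early response genes were higher, with 9 of 12 members positive (0.0144; adjusted p = 0.592 with an estimated correlation). Their sign turned without replicate 1 of wild type at day 16 (adjusted p = 0.985), and the call ended without replicate 2 of the knockdown at that age (0.451). Vascular markers were higher, with 10 of 12 members positive (0.00577; adjusted p = 0.569 with an estimated correlation). Heat shock (0.0393; adjusted p = 0.569 with an estimated correlation), phosphate starvation (0.0393; adjusted p = 0.569 with an estimated correlation) and glucosinolate genes (0.0180; adjusted p = 0.592 with an estimated correlation) were called higher too, with 0 members passing. The calls of these last 3 lists and of the flowering promoters ended with median-of-ratios scaling (adjusted p = 0.0963, 0.0649, 0.0649 and 0.0958). With each library left out, organ identity genes held in the 6 fits in which enough of their members were tested. The others held in 4 (flowering promoters) to 7 (vascular markers) of 8 fits.

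SPL factors of the age pathway were not called at day 16 (camera adjusted p = 0.0642). Adjusted over the list alone, SPL9 (3.77 ± 0.587 and 1.68 ± 0.0707 RPKM, limma adjusted p = 0.0267) and SPL13B (10.1 ± 1.97 and 3.26 ± 1.202 RPKM, adjusted p = 0.00572) were lower. Floral repressors were not called either (0.0853), and 1 of their 14 members, SVP, fell. The 14 lists without a call had camera adjusted p of 0.0527 to 0.504. SPL3 (20.3 ± 9.13 and 15.2 ± 2.61 RPKM), SPL4 (1.96 ± 0.665 and 2.09 ± 0.205 RPKM), FLC (9.93 ± 1.28 and 12.4 ± 1.27 RPKM) and LFY (0.450 and 0.300 RPKM in wild type, 0.230 and 1.00 in the knockdown line) did not pass in limma (adjusted p = 0.849 to 0.969). The number of genes passing was 11 without replicate 1 of wild type, 11 without replicate 2 of wild type and 11 without replicate 1 of the knockdown at day 16. It was 11 with no filter, 12 with quantile normalization and 6 with voom on estimated reads. SVP, PRXR1, PIN1AT, PCC1, AT3G22235 and AT2G25510 passed under all 20 alternatives. SEP3 did not pass when any of the 4 libraries of day 16 was left out (adjusted p = 0.0695 to 0.239), nor with pseudocount 4 (0.0900) or no filter (0.117). With voom, SEP3, AT2G13547 and AT1G25180 (adjusted p = 0.259 each), QQS (0.0621) and AT3G01345 (0.0698) did not pass. AT5G25570 passed under 11 of the 20.

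**Figure D2:**
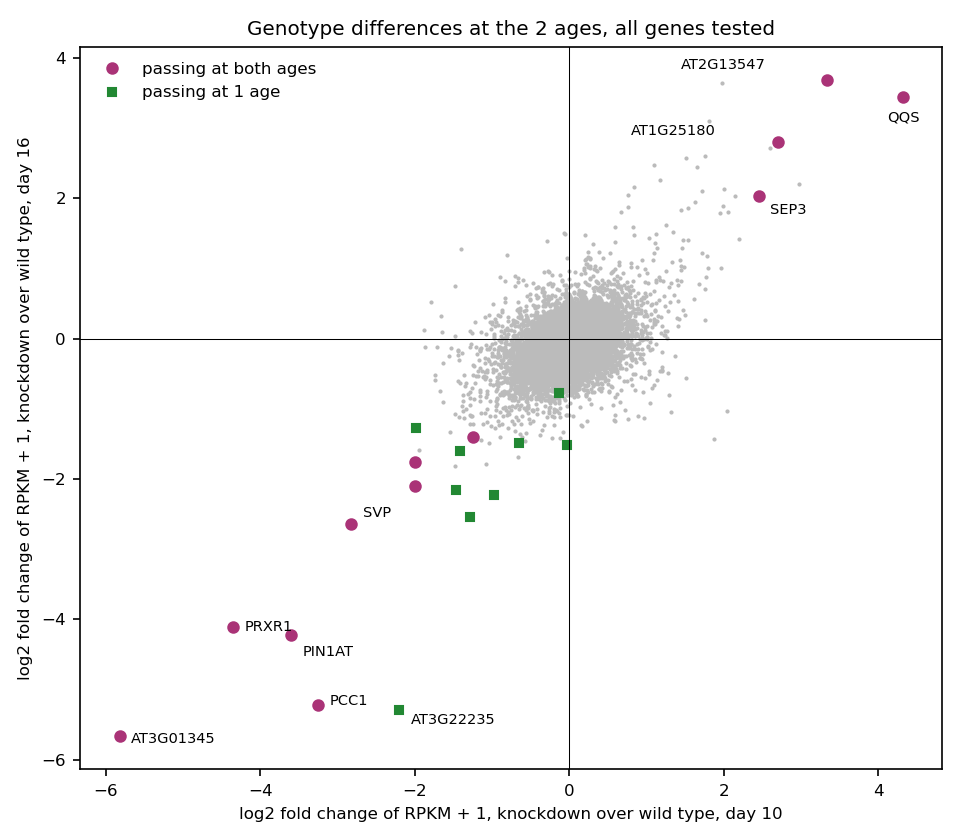
Log2 fold change of the knockdown line over wild type at day 10 (horizontal axis) and day 16 (vertical axis) on the log2(RPKM + 1) scale, with a point per tested gene. Genes that passed at both ages, such as SVP, PRXR1 and QQS, lie far from 0 on the same side of both axes.

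Across both ages, 43 genes passed in the mean of the genotype contrasts, 12 higher and 31 lower in the knockdown line (limma, 2093 genes at an unadjusted p under 0.05). Besides SVP (log2 fold change -2.74 ± 0.145, SE; adjusted p = 1.7e-05) and SEP3 (2.24 ± 0.182; 0.000414), they included GA20OX2 and the ethylene response factor gene EBP, which rose (1.21 ± 0.192; 0.0447 and 0.77 ± 0.113; 0.0357). In 37 of the 43 genes all 4 knockdown libraries lay beyond all 4 wild-type libraries, an order that selecting genes on these same libraries favours. Of the 21 genes that passed at either age, 12 passed at both, 0 in opposite directions, and 19 passed in the mean, which added 24 genes. All 4 genes higher at day 10 were the 4 higher at day 16 (Fisher's exact test for a larger overlap, p = 2.6e-16), and 8 of the 9 lower genes were among the 16 lower at day 16 (5.4e-25). Independent lists would share 0.000916 and 0.00824 genes. These contrasts share no library, but they share 1 estimate of the spread per gene. A gene with a small estimate passes more easily at both ages, so the lists are not independent in the way the Fisher test assumes. The fold changes of the 2 contrasts correlated across genes at a Spearman rho of 0.445, with genes not being independent replicates.

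In the mean of both ages, floral repressors were lower with 12 of 14 members negative (camera adjusted p = 0.0161; adjusted p = 0.540 with an estimated correlation), and organ identity genes were higher (0.00178; adjusted p = 0.540 with an estimated correlation). Adjusted over the list alone, 2 organ identity members were higher, SEP3 and the petal and stamen gene PI (log2 fold change 0.71 ± 0.223, limma adjusted p = 0.0201). Flavonoid genes were lower (0.000719; adjusted p = 0.540 with an estimated correlation), with 9 of 10 members negative and 6 lower adjusted over the list alone. Salicylic acid defence genes were lower (0.0183; adjusted p = 0.540 with an estimated correlation), with WRKY70 and WAK1 lower adjusted over the list alone. Cell division genes were lower, 20 of 21 members being negative (0.0183; adjusted p = 0.579 with an estimated correlation), and auxin genes were higher (0.0120; adjusted p = 0.579 with an estimated correlation). Mesophyll markers were lower (0.0155; adjusted p = 0.579 with an estimated correlation), a call that ended with median-of-ratios scaling (adjusted p = 0.163), and vascular markers were higher (0.00278; adjusted p = 0.540 with an estimated correlation). The 14 lists without a call had camera adjusted p of 0.0546 to 0.946. Among them the 20 measured genes of phospholipid synthesis had 16 negative members and 0 passing (0.131). Their median log2 fold change was -0.11, where that of all genes was -0.064. SPL9 and SPL13B (limma, adjusted over the list alone, adjusted p = 0.00377 each) and 1 gibberellin catabolism gene, GA2OX1 (0.0236), were lower without passing over all genes. With each library left out, the call of organ identity genes held in the 6 fits in which enough of their members were tested. The others held in 4 (cell division) to 7 (floral repressors, flavonoid genes and vascular markers) of 8 fits.

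The count of 43 was 18 without replicate 1 of the knockdown at day 10 and 24 with no filter. It was 27 without replicate 1 and 20 without replicate 2 of wild type at day 10, 20 without replicate 1 of wild type at day 16, 21 and 24 without replicates 1 and 2 of the knockdown at day 16, and 20 with voom on estimated reads.

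**Figure D3:**
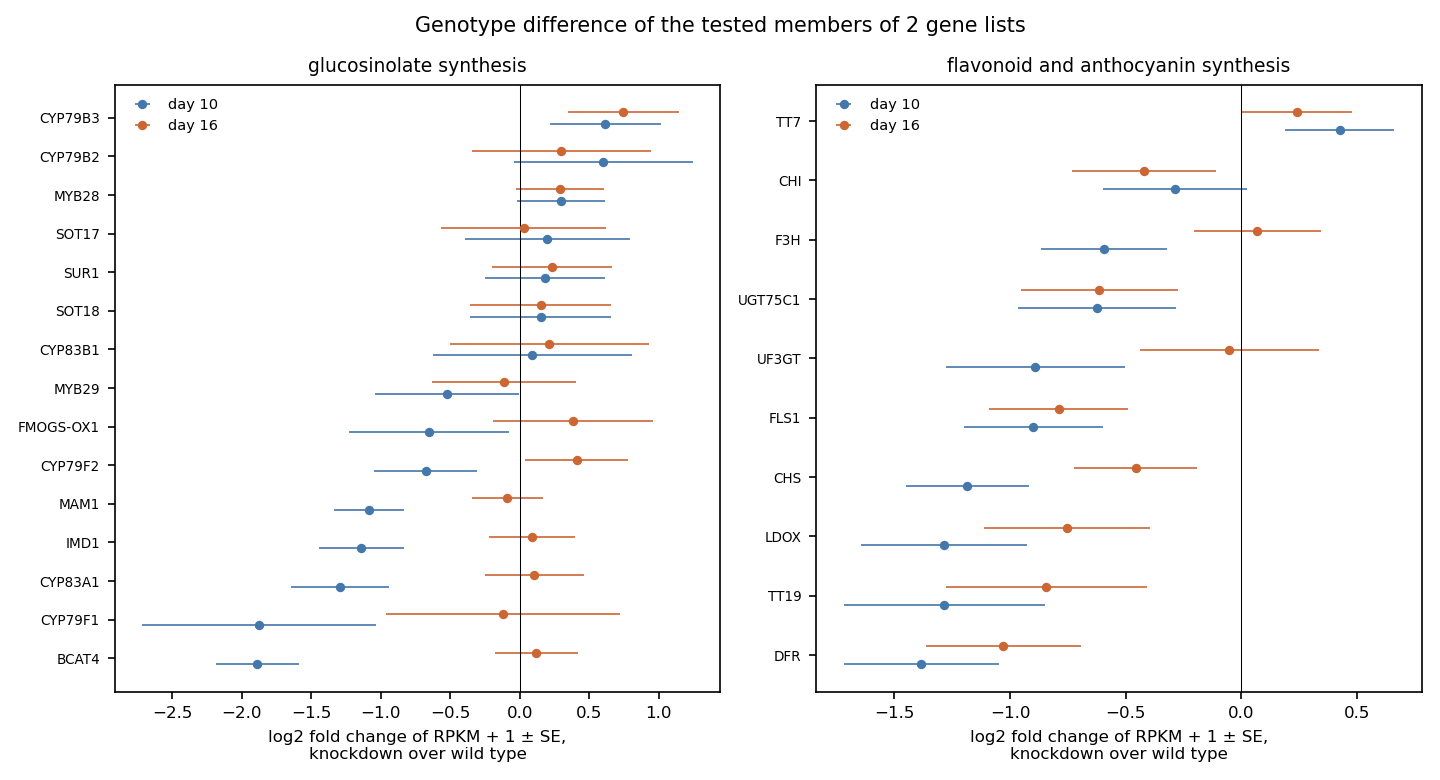
Log2 fold change (on RPKM + 1, ± SE) of the knockdown line over wild type for the tested members of the glucosinolate and flavonoid lists at day 10 and day 16. BCAT4, MAM1, IMD1 and CYP83A1 are negative at day 10 and near 0 at day 16, while DFR, LDOX and FLS1 are negative at both ages.

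The difference of the genotype effect between the ages was tested as an interaction. No gene passed (0 of 17467 in limma with Benjamini-Hochberg adjustment, and 0 with voom on estimated reads). At an unadjusted p under 0.05 there were 288 genes in limma, where chance gives 873. With fewer small p-values than chance gives, the 0 does not show that the genotype effect was equal at both ages. The genes with the smallest p were, on the higher side, BCAT4 of glucosinolate synthesis, with a log2 difference of 2.00 ± 0.422 (SE), AHP4, a phosphotransfer gene of cytokinin signalling (1.60 ± 0.363), AT4G33550 and AT5G42200. On the lower side they were AT3G22235 (-3.08 ± 0.529), PCC1 (-1.96 ± 0.466), the cutinase gene CDEF1 and AT5G55450, all at an adjusted p of 1.00. Adjusted over its list alone, BCAT4 differed (limma adjusted p = 0.0124). It had 61.1 RPKM in wild type and 15.8 in the knockdown line at day 10, and 132 and 132 RPKM at day 16. Glucosinolate genes as a group had a higher genotype effect at day 16 than at day 10 (camera adjusted p = 5.3e-08; adjusted p = 0.965 with an estimated correlation), with 11 of 15 members positive. Flavonoid genes (8 of 10 positive, 0.00239; adjusted p = 0.965 with an estimated correlation) and endoplasmic reticulum stress genes (12 of 20 positive, 0.00239; adjusted p = 0.965 with an estimated correlation) were called in the same direction. With each library left out they held in 8 (glucosinolate), 5 (flavonoid) and 6 (endoplasmic reticulum stress) of 8 fits. The other 19 lists were not called (0.0509 to 0.955).

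Between day 10 and day 16 in wild type, AGL24, a MADS-box promoter of flowering, rose from 1.63 ± 0.311 to 18.4 ± 0.347 RPKM (SD, n = 2). EXT4, a cell wall extensin gene, rose from 3.73 ± 0.891 to 54.2 ± 17.44 RPKM and DR4 from 16.0 ± 1.499 to 150 ± 33.4 RPKM, while XTH7, which encodes a xyloglucan-modifying enzyme, fell from 254 ± 10.3 to 86.0 ± 5.56 RPKM. SOC1, a floral integrator, and SPL3 were higher adjusted over the list alone (4.45 and 9.24 RPKM, limma adjusted p = 0.0157; 5.50 and 20.3 RPKM, adjusted p = 0.00202) without passing over all genes (adjusted p = 0.358 and 0.0881).

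In limma, 39 genes passed, 34 higher and 5 lower at day 16 (1303 at an unadjusted p under 0.05, median log2 fold change of all genes 0.10, or 0.003 with median-of-ratios scaling). The log2 fold change was 2.89 ± 0.214 (SE) for AGL24, 3.52 ± 0.256 for EXT4, 3.13 ± 0.226 for DR4 (adjusted p = 0.000694 each), 2.94 ± 0.266 for AT1G67860 (0.00219) and -1.55 ± 0.144 for XTH7 (0.00240). AT5G51190, listed at 0 and 0.180 RPKM at day 10 and at 12.2 and 8.92 RPKM at day 16, rose (0.00219). AT1G52100, AT5G26280 and the Rubisco small subunit gene RBCS1B fell (-1.24 to -1.09). The age count was 12 with no filter, 18 with median-of-ratios scaling, 16 without trend, 22 with only these 4 libraries in the fit, and 22 with voom on estimated reads. It was 13, 10, 15 and 7 without replicates 1 and 2 of wild type at day 10 and replicates 1 and 2 of wild type at day 16. RBCS1B passed under 7, AT1G52100 under 10 and AT5G26280 under 13 of 20 alternatives.

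Heat shock and endoplasmic reticulum stress genes were not called with age in wild type (camera adjusted p = 0.4565 and 0.1053), while other stress lists were higher at day 16. Touch and rapid stress response, which handling also induces, was among them (14 of 16 members positive, 1 passing; camera adjusted p = 4.1e-07; adjusted p = 0.486 with an estimated correlation). The others were abscisic acid, cold and drought (16 of 17, 0 passing; 2.3e-06; adjusted p = 0.486 with an estimated correlation), jasmonate and wounding (19 of 19, 0 passing; 0.00193; adjusted p = 0.516 with an estimated correlation) and salicylic acid defence (10 of 11, 1 passing; 0.00193; adjusted p = 0.486 with an estimated correlation). The passing members were ERF5, an ethylene response factor gene (2.24 ± 0.537 and 13.4 ± 0.834 RPKM), and PR5, a pathogenesis-related gene (4.90 ± 0.0566 and 15.4 ± 0.318 RPKM). Glucosinolate genes (14 of 15 positive; 0.00529; adjusted p = 0.516 with an estimated correlation) and autophagy genes (13 of 13 positive; 0.0177; adjusted p = 0.516 with an estimated correlation) were higher as well. Mesophyll markers were lower, 20 of 21 being negative and 1 passing (4.7e-13; adjusted p = 0.486 with an estimated correlation). Cell division (17 of 21 negative; 0.00108; adjusted p = 0.516 with an estimated correlation), flavonoid (7 of 10 negative; 0.0139; adjusted p = 0.516 with an estimated correlation) and organ identity genes (3 of 4 negative; 0.0161; adjusted p = 0.486 with an estimated correlation) were lower. The last 2 calls ended with median-of-ratios scaling (adjusted p = 0.0587 each). With each library left out, touch, abscisic acid, jasmonate and mesophyll calls held in all 8 fits, salicylic acid defence in 7, organ identity in 4 of 6 and the others in 6 of 8. The median log2(RPKM + 1) of the abscisic acid list was 2.40 and 3.01 at day 10 and 3.01 and 4.43 at day 16. At the median, replicate 1 of day 16 was thus level with replicate 2 of day 10. The other 12 lists were not called (camera adjusted p = 0.0525 to 0.925).

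In the knockdown line, AGL24 rose from 1.34 ± 0.339 RPKM at day 10 to 14.96 ± 0.347 at day 16, DR4 from 22.0 ± 6.11 to 200 ± 31.6 and EXT4 from 3.34 ± 0.325 to 34.2 ± 5.93 (SD, n = 2). XTH7 fell from 261 ± 40.8 to 89.8 ± 1.53 RPKM, and SEP3 fell from 20.4 to 5.38 RPKM. BCAT4 rose from 15.8 ± 2.39 to 132 ± 1.55 RPKM and MAM1 of the same glucosinolate branch from 44.4 ± 0.686 to 168 ± 5.64 RPKM. Adjusted over the list alone, SOC1 (limma adjusted p = 0.00648), FD (0.0357), SPL3 (0.0435), SPL13A (0.00800), FLC (0.00749), SVP (0.0368) and TEM1 (0.0368) were higher at day 16. For SVP the values were 3.85 and 6.88 RPKM.

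In limma, 47 genes passed, 41 higher and 6 lower (1493 at an unadjusted p under 0.05). The log2 fold change was 2.78 ± 0.214 (SE) for AGL24 (adjusted p = 0.00143), 3.14 ± 0.226 for DR4 (0.00143), 2.99 ± 0.298 for BCAT4 (0.00392), -1.75 ± 0.258 for SEP3 (0.0295), -1.52 ± 0.144 for XTH7 (0.00294) and 3.37 ± 0.556 for HIS1-3, a linker histone gene (0.0498). AT5G51190, listed at 0 in both libraries at day 10 and at 16.0 and 8.73 RPKM at day 16 (0.00143), and AT1G48750, listed at 0 and 0.110 against 55.4 and 26.3 RPKM (0.00805), rose. AT5G26280 and AT1G52270 fell (-1.65 and -1.46). Of the genes that passed, 21 higher and 3 lower were shared with wild type (Fisher's exact test for a larger overlap, p = 1.0e-49 and 2.2e-10). Independent lists would share 0.0798 and 0.00172 genes, but these contrasts too share the estimate of the spread per gene. The fold changes of the 2 age contrasts correlated across genes at a Spearman rho of 0.482. The count was 15 with no filter, 30 without trend, 27 with only these 4 libraries in the fit and 77 with robust moderation. It was 25, 19, 22 and 16 without replicates 1 and 2 of the knockdown at day 10 and replicates 1 and 2 at day 16. SEP3 did not pass when any of these 4 libraries was left out (adjusted p = 0.112 to 0.160). HIS1-3 passed under 5, SEP3 and AT1G52270 under 13 each and AT1G48750 under 15 of 20 alternatives.

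Glucosinolate genes were higher at day 16 in the knockdown line, 15 of 15 being positive and 2 passing (camera adjusted p = 1.0e-11; adjusted p = 0.388 with an estimated correlation). Abscisic acid, cold and drought genes (17 of 17 positive; 1.6e-06; adjusted p = 0.388 with an estimated correlation), phosphate starvation genes (10 of 12; 0.000393; adjusted p = 0.498 with an estimated correlation), and touch genes (10 of 16, with ERF5 passing; 0.00119; adjusted p = 0.551 with an estimated correlation) were higher. So were flowering promoters (5 of 7, with AGL24 passing; 0.00490; adjusted p = 0.388 with an estimated correlation) and salicylic acid defence genes (8 of 11, with PR5 passing; 0.0105; adjusted p = 0.551 with an estimated correlation). Jasmonate genes were called higher with 16 of 19 positive (0.0365; adjusted p = 0.684 with an estimated correlation). Their sign turned without replicate 1 of the knockdown at day 10 (adjusted p = 0.602) and without replicate 2 of the knockdown at day 16 (0.389), and the call ended with median-of-ratios scaling (0.0622). Mesophyll markers were lower, with RBCS1B and RBCS2B passing (7.8e-06; adjusted p = 0.574 with an estimated correlation), as were cell division genes (19 of 21 negative; 0.0117; adjusted p = 0.684 with an estimated correlation). With each library left out, glucosinolate and abscisic acid calls held in all 8 fits and the others in 6 or 7. The median log2(RPKM + 1) of the abscisic acid list was 3.06 and 2.79 at day 10 and 3.01 and 5.67 at day 16, so the second library of day 16 stood apart. The other 13 lists were not called (0.0994 to 0.895).

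The authors' deposited tables list 320 loci as higher and 331 as lower in the knockdown line at day 10, and 209 and 213 at day 16. The largest folds among the named genes of these tables were 3462.52 for AT1G32630, 1037.98 for AT2G13547 and 914.94 for AT1G04560 at day 10, and 1345.03 for AT3G54940, 1329.81 for M17 and 998.82 for AT4G02725 at day 16. On the lower side the authors' deposited tables give -134.08 for AT3G01345, -28.9 for PCC1 and -20.65 for PRXR1 at day 10. At day 16 the authors' deposited table of lower genes gives -382.85 for AT3G01345, -56.19 for AT3G22235 and -55.27 for PCC1. SVP stands in the authors' deposited tables at -8.49 for day 10 and -6.42 for day 16, and SEP3 at 7.09 and 10.37. Means of the RPKM values had the listed direction for 94.6% and 91.1% of the loci higher and lower at day 10 and for 91.8% and 95.2% of those at day 16. The tables were deposited with these same libraries, so the agreement in direction is no independent check. Of the loci in these 4 tables, 250, 256, 151 and 166 were tested in limma, and 3, 8, 3 and 11 passed in the listed direction. At an unadjusted p under 0.05 there were 100, 167, 83 and 126 in that direction. The tables of the 2 ages share 74 higher and 70 lower loci, where independent lists would share 2.42 and 2.55.

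The listed folds and the RPKM values lay within 1 log2 unit of each other for 265, 276, 171 and 181 of the 4 tables' loci and more than 2 log2 units apart for 23, 23, 21 and 4. AT1G32630 had 5.51 ± 0.304 RPKM in wild type and 7.54 ± 3.05 in the knockdown line at day 10, and AT4G02725 29.3 ± 2.62 and 29.3 ± 2.56 RPKM at day 16. AT1G04560 was listed at 0 in both wild-type libraries of day 10 and at 14.8 and 0 RPKM in the knockdown line, and AT3G54940 was listed at 0 in both wild-type libraries of day 16 and at 1.95 and 10.9 RPKM in the knockdown line. M17, a late embryogenesis gene, was listed at 0 in both wild-type libraries of day 16 and at 0.280 and 16.8 RPKM in the knockdown line. None of these last 5 genes passed in limma (adjusted p = 0.678 to 1.00).

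**Figure D4:**
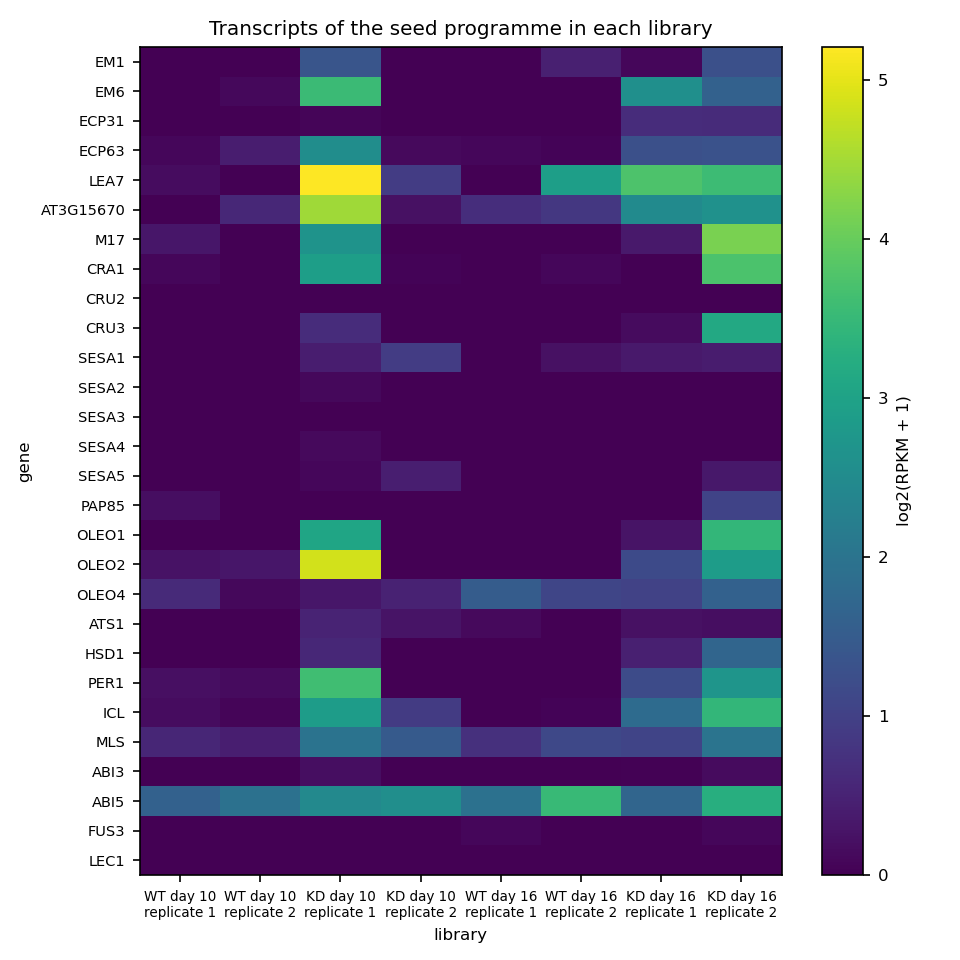
Log2(RPKM + 1), as colour, of 28 transcripts of the seed programme in each of the 8 libraries of wild type (WT) and the knockdown line (KD). LEA7, OLEO2 and M17 are high in some but not all knockdown libraries.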

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

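No test in this part was chosen after its result was seen. The genotype effect differed between the ages for 3 gene lists (interaction, camera). Glucosinolate genes, which make sulfur-rich defence compounds, had an adjusted p of 5.3e-08 (adjusted p = 0.965 with an estimated correlation), flavonoid and anthocyanin genes 0.00239 (adjusted p = 0.965 with an estimated correlation) and endoplasmic reticulum stress genes 0.00239 (adjusted p = 0.965 with an estimated correlation). For 5 named genes the knockdown libraries lay on opposite sides of wild type at the 2 ages, without passing for the interaction in limma (adjusted p = 1.00 each). The log2 difference of the genotype effect between the ages was 1.60 for AHP4, 2.23 for AT4G33550, 0.69 for FD, 0.68 for FLC and -0.72 for AT1G52270. The authors' deposited tables name 15 loci that the table of RPKM values does not list, so their values could not be compared. One of the 15 is AT1G25175, chosen after its value was seen because it overlaps AT1G25180; the authors' deposited tables give it a fold of 13.73 at day 10 and 40.84 at day 16.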

How the results depend on the processing

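No test in this part was chosen after its result was seen except voom on estimated reads. The planned edgeR and DESeq2 tests were not run, because whole reads were not recovered for enough genes. Of 840 values of the 42 single-gene results that passed, 731 stayed past the threshold, 109 did not and 0 changed sign; of 1028 values of results that had not passed, 18 did. PECT1 kept its sign without passing in all 20 alternatives, at a log2 fold change of -0.17 to -0.10 at day 10 and -0.24 to -0.05 at day 16. The interaction stayed at 0 genes in all 20.

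The 13 genes of day 10 became 20 with the replicate block and 7 with voom. Leaving out a library gave 7 (replicate 2 of wild type at day 10) to 26 (replicate 2 of the knockdown at day 10, 17 higher and 9 lower). The 20 genes of day 16 (4 higher, 16 lower) became 11 with no filter, 12 with quantile normalization (4 higher, 8 lower) and 6 with voom (0 higher, 6 lower). They became 11 without replicate 1 of wild type, 11 without replicate 2 of wild type and 11 without replicate 1 of the knockdown at that age. The 43 genes of the mean of both ages became 24 with no filter, 68 with the block and 20 with voom. Without replicate 2 of the knockdown at day 10 they were 48, the highest. Without replicates 1 and 2 of wild type at day 10 they were 27 and 20, without replicate 1 of wild type at day 16 20, without replicate 1 of the knockdown at day 10 18, and without replicates 1 and 2 of the knockdown at day 16 21 and 24. The 12 genes shared by both ages became 3 with voom and 7 without replicate 2 of wild type at day 10, and at most 14 with a library left out (replicate 2 of the knockdown at day 10). Over the authors' 4 deposited tables, 25 entries passed in the listed direction in limma and 12 with voom. A locus that stands in the tables of both ages counts at each age.

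The 39 age genes of wild type became 12 with no filter, 18 with median-of-ratios scaling, 16 without trend, 89 with the block, 22 with voom and 22 in a fit on only these groups. They were 13 and 10 without replicates 1 and 2 of day 10 and 15 and 7 without those of day 16, and at most 54, without replicate 2 of the knockdown at day 10. The 47 age genes of the knockdown line became 15 with no filter, 30 without trend, 77 with robust moderation, 109 with the block and 27 in a fit on only these groups. They were 25 and 19 without replicates 1 and 2 of day 10 and 22 and 16 without those of day 16, and at most 53, without replicate 1 of wild type at day 16.

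The 45 calls of gene lists (28 higher, 17 lower) became 0 with an estimated correlation, 2 with fry and 29 without replicate 2 of the knockdown at day 16, and at most 51 with a library left out (replicate 1 of wild type at day 10). The sign turned for mesophyll markers at day 10 without replicate 2 of the knockdown (adjusted p = 0.688), for auxin genes at day 16 without replicate 1 of wild type (0.985), and for jasmonate genes with age in the knockdown line without replicate 1 of day 10 (0.602) or replicate 2 of day 16 (0.389). Few calls of lists held with every library left out. They were floral repressors, organ identity and flavonoid genes at day 10, organ identity genes at day 16 and in the mean of both ages (organ identity with 6 of the 8 libraries, as the list had too few tested members without the others), and glucosinolate genes in the interaction. With age they were mesophyll, touch, abscisic acid and jasmonate genes in wild type, and glucosinolate and abscisic acid genes in the knockdown line. With the other replicate of these groups left out, the same 3 lists had an adjusted p of 2.8e-09 (mesophyll, replicate 1 of the knockdown), 2.5e-06 (auxin, replicate 2 of wild type) and 9.6e-07 (jasmonate, replicate 2 of day 10).

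With no filter more genes share the adjustment, and with a library left out fewer samples carry the test and the lone sample of its group is assumed to vary like the other groups; for the other changes the cause was not tested. The replicate numbers were not taken as pairs in the leading test, since the labels name no shared origin and not every pair of groups had correlated deviations (-0.239 to 0.329, over 0.1 in 4 of 6). With 6 of 8 libraries closest to their own number and 38 genes in the split by number, a structure that follows the numbers is not excluded. In the first of these measures the 2 libraries of a group mirror each other, so they always give the same answer. At 15.46 to 18.17 M reads, genes such as FT and AP1 were too low to test.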

Other observations

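The 3 tests on SVP and the dry seed test were chosen after the results they address were seen; the other tests were planned before unless stated below. The list of seed transcripts, which the abscisic acid test also addresses, and the sulfate genes were chosen after their values had been seen.

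Transcripts of the seed programme were higher in sum in 3 of the 4 knockdown libraries than in any wild-type library. Some were present in wild type too, such as LEA7 at 6.56 RPKM in the second library of day 16 and ABI5 at 2.08 to 10.37 RPKM in all 4. The summed RPKM of 28 such transcripts was 149 and 10.7 in the knockdown line and 4.2 and 4.6 in wild type at day 10, and 35 and 108 in the knockdown line and 6.2 and 20.7 in wild type at day 16. The oil body protein gene OLEO2 was listed at 27.9 and 0 RPKM in the knockdown line at day 10 and at 1.26 and 6.37 RPKM at day 16, and the storage globulin gene CRA1 at 6.59 and 0.0300 and at 0 and 12.4 RPKM. The mean log2(RPKM + 1) of these transcripts was 1.064 ± 0.654 in the 4 knockdown and 0.214 ± 0.105 in the 4 wild-type libraries (SD, n = 4). The authors' deposited tables list 12 of the 28 as higher at day 10 and 13 at day 16, and 0 as lower. None of the tested members passed in limma at either age or in the mean (lowest adjusted p = 0.123, ICL).

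Seed material in the dissected samples could bring such transcripts, in which case the 2S albumins, among the most abundant seed transcripts, should be present too. In these 3 libraries the 2S albumins and CRU2 reached at most 0.33 RPKM, next to 35.9, 12.5 and 10.8 RPKM of the late embryogenesis gene LEA7, but other storage globulin genes were higher, CRA1 at 6.59, 0 and 12.4 RPKM and CRU3 at 0.590, 0.110 and 7.84 RPKM, so dry seed remains open. A response of the seedling to abscisic acid might also bring them. The median log2(RPKM + 1) of the abscisic acid list was 3.06 and 2.79 in the knockdown line and 2.40 and 3.01 in wild type at day 10, and 3.01 and 5.67 in the knockdown line and 3.01 and 4.43 in wild type at day 16, so this test cannot tell.

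SVP was low in all 4 knockdown libraries. Scaling between libraries could shift a gene, but with median-of-ratios scaling the log2 fold change at day 16 was still -2.51. Loss of a stretch of chromosome around SVP should lower its neighbours, and the lowest mean log2 fold change of the 10 nearest tested genes was -0.42. Reads of SVP could have been assigned to its relative AGL24, but AGL24 changed by -1.85 RPKM in the mean of both ages while SVP lost 35.5 RPKM. An effect of the knockdown itself and a lesion or off-target effect specific to this 1 line remain open, and no test here separates them.

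Of 1057 values in the authors' deposited tables with an RPKM ratio, 71 lay more than 2 log2 units from that ratio, taken with 0.01 RPKM added to both means. Of the 70 with an adjacent gene in the table, 56 (80.0%) lay within 1 log2 unit of such a gene's RPKM ratio. The listed folds were shuffled 10000 times within age and direction. This gave a median of 23 and at most 37 (permutation test, p = 0.0001, the smallest possible). Some loci, such as AT5G40410, stand among these values at both ages, and the test treats them as independent. With nothing added and only genes above 0 in both groups, a check made after the result was seen, 35 of 48 matched an adjacent gene, against a highest count of 26 in the shuffles. These folds are likely those of neighbouring or overlapping genes. For example, the authors' deposited table of day 10 gives 66.35 for AT5G40410, which had 0.970 and 1.26 RPKM and lies next to OLEO2. Low expression might add to the mismatch. Loci under 1 RPKM in both groups gave 28.2% of the differing values and 22.4% of the others (Fisher's exact test, two-sided p = 0.304). This test, which also treats repeated loci as independent, cannot tell.

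The genotype count was compared with all 35 splits of the 8 libraries into 4 and 4, with age as a term in all but the split by age itself. Genotype gave 58 genes, and 2 of the 35 splits gave as many, genotype itself and the split by age with 243; the split by replicate number gave 38 and the other 32 at most 3. The count of the split by age comes from a fit of another form and points to a structure of the samples by age. The share of 0.057 over all 35, the form planned in advance, is set by that split, so it is no guide to chance here. Among the 34 splits with age as a term, a comparison chosen after the result was seen, genotype gave the most, with 38 the highest of the others. The 2 genotype contrasts, which share no library but share the estimate of the spread per gene, had 12 passing genes in common. Of the 43 genes that passed in the mean of both ages, 7 had another within 50 kb, against a median of 2 in 1000 random draws (share of draws as high 0.017). For age the counts were 8 of 39 in wild type (0.005) and 4 of 47 in the knockdown line (0.297).

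Genes of sulfate assimilation differed between the 2 wild-type libraries of day 10. APR3, an adenylylsulfate reductase gene, was at 9.81 and 88.1 RPKM there and at 5.55 to 17.38 RPKM in the other 6 libraries, APR2 at 10.5 and 64.7 RPKM, and AT1G04770 at 1.85 and 20.2 RPKM. MYC2, a jasmonate transcription factor gene that overlaps AT1G32630, was listed at 0 and 0 RPKM in wild type at day 10, 7.94 and 7.34 in wild type at day 16, 0 and 15.9 in the knockdown line at day 10, and 0 and 16.8 at day 16.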
